A study of Mus musculus with 6 samples.

How the data were processed

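Poly(A) RNA was profiled in 6 libraries of bone marrow-derived macrophages (BMDMs) of the C57BL/6 mouse strain, which are primary macrophages grown from bone marrow. In 3 libraries the cells had received a negative-control siRNA (siNC) and in 3 an siRNA against Piezo1 (siPiezo1). The cells of all 6 libraries were stretched for 4 h. Per the labels' protocols, the libraries were made with dUTP strand marking and sequenced as paired-end reads on a NovaSeq instrument. Each sample was placed in its group by its title, and 0 columns of values were left unmapped.

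Per the submitters' processing notes, the reads were handled with cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d, the build was GRCm39, and DESeq2 and edgeR were also named. The role of each tool, the annotation release and whether counting used the strand are not given in the sources used here. The deposited values are whole-number estimated counts per Ensembl gene for 55401 genes, with no scaling between samples. The estimated counts are not whole reads or fragments: low values pile up at multiples of 3.75 to 3.79 counts, so 1 fragment was worth about 4 counts. The totals of 61086684 to 75052745 counts per library therefore stood for about 16.2 to 19.8 M fragments. The design written before the data were examined assumed counts; the unit was treated as estimated counts, which were already whole and needed no rounding, and the same test was used.

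Genes were named by Ensembl identifier from a GENCODE M21 table, which matched 55141 of the 55401 identifiers. The unmatched identifiers held at most 0.00886% of a library's counts. Coordinates are not given, because the annotation used here is of another build than the one in the processing notes. A total of 107 symbols were shared by more than 1 identifier.

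Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group, which left 15959, and library sizes were scaled with TMM factors of 0.988 to 1.028. The main test was edgeR's quasi-likelihood test with robust dispersion estimates on all 6 libraries, with the group as the only term. P-values were adjusted by Benjamini-Hochberg over the tested genes, with a threshold of 0.05. Log2 fold changes are siPiezo1 against siNC, and their standard errors (SE) were taken as the size of the fold change divided by the square root of the F statistic. CPM, each count scaled to a common library total, was computed with the TMM factors. For single genes of the axis named in the series title, an exact two-sided permutation test of CPM was run, whose smallest possible p is 0.1 with 3 against 3 libraries. Nothing in the labels says that the replicates are separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

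A total of 38 gene lists, with 810 entries, was fixed before the data were examined. They cover cell cycle, PI3K-AKT signalling, mechanical sensing, macrophage states, metabolism, stress responses and markers of other cell types. Each list with at least 5 tested members was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Camera compares a list with all other genes, and fry asks whether a list's genes move, on balance, 1 way.

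Named genes were chosen by a rule fixed before the data were examined. It takes Piezo1, Ccnd1 and kinase genes of the axis named in the series title; the 10 largest rises and the 10 largest falls among symbol-named genes past the threshold with at least 5 CPM in the higher group and no overlap between groups; up to 4 members with the smallest p of each list past the camera threshold or with at least 3 members past the gene threshold; the 5 genes with the smallest adjusted p; and up to 2 members with the smallest p of each list with no member past the threshold. Predicted gene models were left out of the largest rises and falls, and no gene of the 6-library test then met that part. The same part was therefore applied to the test without siNC replicate 2, and list members past the threshold there were also taken. That choice, and the siNC replicate 2 genes given with the description of the libraries, were made after the data were seen.

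The alternatives were DESeq2's size factors, library totals alone, no filter on low counts (at least 1 count in total), at least 50 counts in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, a threshold of 0.01, a 2-fold minimum, a test against a fold of 1.2, summed rows of shared symbols, and each library left out in turn. Counts divided by 4 and limma-voom with library weights were added after the data were seen.

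The test was checked on simulated counts for the same 15959 genes with 200 genes changed. With 3 against 3 libraries it called 3.0%, 49.3% and 93.9% of genes changed 1.5-fold, 2-fold and 4-fold, and 3.0% of its calls were false. With 2 siNC against 3 siPiezo1 libraries the shares called were 22.4%, 74.6% and 95.5%, and 13.5% of the calls were false, above the nominal level.

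Near-identical copies of 133 named genes were searched with BLAST 2.17.0 among GENCODE M21 transcripts, at 95% identity over at least 300 bases, and overlapping exons were read from the same annotation. For 8 of these genes the copies held over 10% of the gene's counts. They were Gapdh, Gbp10, Hspa1a, Fcgr3, Bcl2a1b, Rps2, H2-DMb1 and Pik3cb, whose counts are uncertain. Figures were drawn with matplotlib 3.10.9.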

Results

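Gene expression was measured by RNA sequencing in mouse bone marrow-derived macrophages to ask how Piezo1, a mechanically gated cation channel, promotes macrophage proliferation under mechanical stimuli. The study's title names a PI3K-AKT-Ccnd1 axis. Cells were transfected with a negative-control siRNA (siNC, 3 libraries) or an siRNA against Piezo1 (siPiezo1, 3 libraries), and all were stretched for 4 h. The single comparison is therefore siPiezo1 against siNC under stretch, and unstretched cells were not analysed here. Total estimated counts were 61086684, 73573829 and 67713888 in siNC replicates 1, 2 and 3, and 72421840, 75052745 and 67058765 in siPiezo1 replicates 1, 2 and 3.

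Macrophage transcripts were abundant in every library, with Lyz2, which encodes lysozyme, at 20623 to 26818 CPM. One library, siNC replicate 2, stood apart from the other 5. Its log2 CPM correlated across genes at 0.938 to 0.951 with the other libraries, against 0.958 to 0.969 for the pairs without it. Among 9116 genes with at least 10 CPM in siNC 2 or on average in the others, 229 were more than 2-fold above, and 94 more than 2-fold below, all other libraries in siNC 2. In the other libraries the counts made the same way were 1 to 8 genes above and 10 to 20 below. The chemokine gene Ccl2 stood at 598 CPM in siNC 2, against 16.9 and 17.5 in siNC 1 and 3. Also higher in siNC 2 were the chemokine gene Cxcl3 (282 against 10.9 and 11.4) and the cytokine gene Il1b (292 against 16.8 and 18.2). So were S100a9 (1044 against 181 and 208) and Ngp (609 against 157 and 165), both of the list of neutrophil markers. The proliferation marker Mki67 stood at 391 CPM in siNC 2, against 165 and 174 in siNC 1 and 3 and 195, 238 and 290 in the siPiezo1 libraries. Apoe, a lipid carrier of macrophages, stood at 101 CPM in siNC 2, against 677 and 712 in siNC 1 and 3 and 240 to 257 in siPiezo1. Csf1r, the receptor for the macrophage growth factor M-CSF, stood at 2290 CPM against 4447 and 4547.

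**Figure D1:**
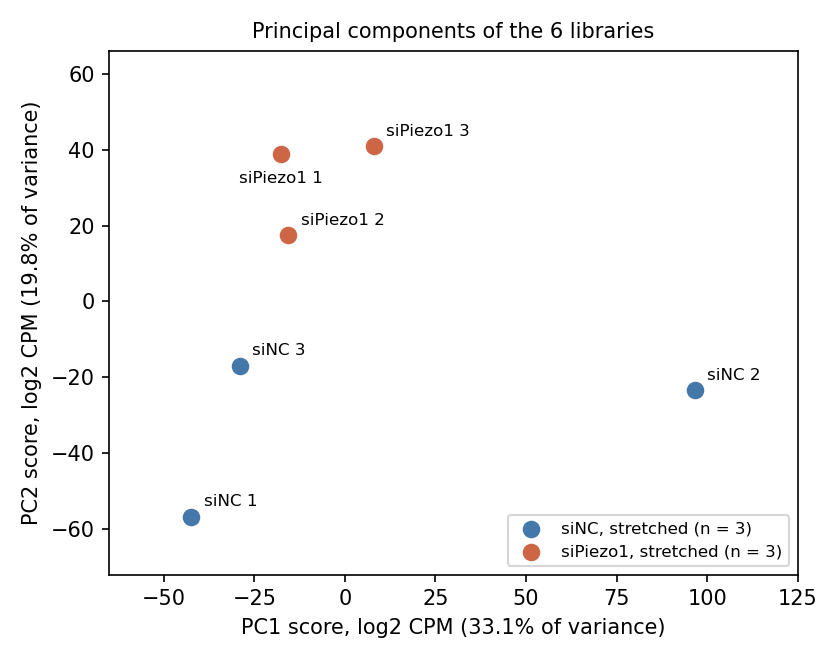
Scores of the 6 libraries on the first 2 principal components of log2 CPM, each point a library and each colour a siRNA group. siNC 2 lies alone on PC1 (33.1% of variance) at 96.7, and the siNC and siPiezo1 libraries lie on opposite sides of 0 on PC2 (19.8%).

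Piezo1, the siRNA target, was lower in each siPiezo1 library than in each siNC library. It stood at 180, 285 and 189 CPM in siNC and at 111, 109 and 113 CPM in siPiezo1, so the siPiezo1 mean was 51.0% of the siNC mean. Ccnd1, which encodes cyclin D1, the G1 cyclin that activates CDK4 and CDK6, stood at 29.1, 53.8 and 30.8 CPM in siNC and at 13.9, 18.5 and 14.2 CPM in siPiezo1, or 40.9% of the siNC mean. The log2 fold change of Piezo1 was -0.97 ± 0.18 (SE) and that of Ccnd1 was -1.29 ± 0.27 (SE). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over all genes, neither passed the threshold (adjusted p = 0.744 for both; unadjusted p = 0.00114 for Piezo1 and 0.00204 for Ccnd1). An exact permutation test gave p = 0.1 for each, the smallest value that 3 against 3 libraries allow. Both genes were highest in siNC 2. Without that library the log2 fold changes were -0.73 ± 0.06 (SE) for Piezo1 and -0.95 ± 0.14 (SE) for Ccnd1. Their adjusted p was then 0.00245 and 0.0267 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Genes at an unadjusted p under 0.05 in that test also rose, from 786 with all 6 libraries to 2291. The lower adjusted p therefore does not rest on the spread of these genes alone. DESeq2 called both with all 6 libraries (adjusted p = 0.000982 for Piezo1 and 0.00269 for Ccnd1, Benjamini-Hochberg), and with edgeR, limma-voom and DESeq2 the alternatives ranged from these values to an adjusted p of 1 for both genes. Exons of LTO1 cover 23.4% of the exon bases of Ccnd1 on the opposite strand; LTO1 stood at 13.7 ± 1.96 CPM in siNC and 15.6 ± 1.85 CPM in siPiezo1 (SD, n = 3).

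The kinase genes of the axis differed less between the groups than Piezo1 and Ccnd1. Akt1 stood at 290 ± 9.23 CPM in siNC and 283 ± 10.7 CPM in siPiezo1 (SD, n = 3), a log2 fold change of -0.03 ± 0.07 (SE). The log2 fold change of Akt2 was -0.07 ± 0.12 (SE). Those of the catalytic PI3K genes were 0.10 ± 0.18 for Pik3ca, -0.05 ± 0.21 for Pik3cb, -0.18 ± 0.12 for Pik3cd and 0.13 ± 0.11 for Pik3cg (SE). Without siNC 2 the sign turned for Pik3ca (-0.06 ± 0.13) and Pik3cb (0.25 ± 0.07, SE), and Akt2 stood at -0.17 ± 0.09. None of these genes passed the threshold of edgeR's quasi-likelihood test, with all 6 libraries or without siNC 2. RNA levels say nothing of the phosphorylation of these kinases.

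Across all genes, 1 of 15959 passed the threshold, and it was lower in siPiezo1. This gene, 1600014C10Rik, fell from 62.3 ± 2.44 CPM in siNC to 22.0 ± 2.23 CPM in siPiezo1 (SD, n = 3), a log2 fold change of -1.50 ± 0.10 (SE, adjusted p = 0.0424 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The call was lost without siNC 1 (adjusted p = 0.366), siNC 3 (0.262), siPiezo1 1 (0.355) or siPiezo1 2 (0.124) in the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and over all alternatives the adjusted p ranged from 3.46e-29 with DESeq2 to 0.997. The next smallest adjusted p-values belonged to Zfp451 (18.3, 19.9 and 20.2 CPM in siNC, 40.1, 38.6 and 42.9 in siPiezo1), Gbp10, Stac2 and Sptan1, a spectrin of the membrane skeleton (267, 256 and 276 CPM in siNC, 168, 166 and 180 in siPiezo1). Their log2 fold changes were 1.06 ± 0.10, 1.70 ± 0.19, 0.79 ± 0.09 and -0.63 ± 0.08 (SE). Without siNC 2 these 4 genes passed the same test (adjusted p = 0.00484, 0.0124, 0.0119 and 0.00375 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The groups did not overlap for any of these 5 genes, and siNC 2 lay beside the other siNC libraries. The counts of Gbp10 are uncertain, since a copy, Gbp6, matches it at 99.2% identity over 3131 bases and held 124 CPM, on library totals, against 6.03 for Gbp10.

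With edgeR's quasi-likelihood test 0 genes were called higher in siPiezo1. At an unadjusted p under 0.05 there were 402 genes higher and 384 lower, DESeq2 called 46 higher and 42 lower, and limma-voom called 0 higher and 1 lower. The groups did not overlap for 1898 genes, or 11.9% of those tested, where chance gives 10%.

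**Figure D2:**
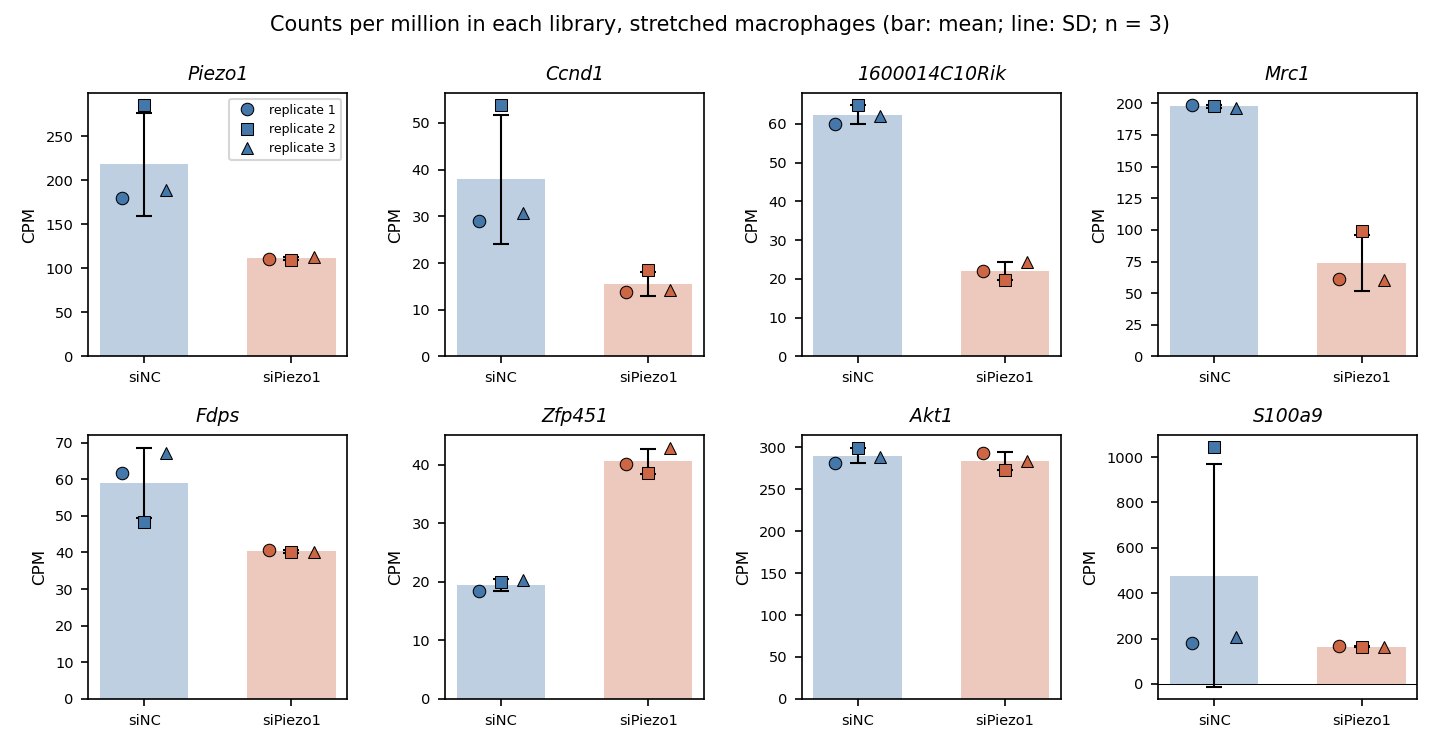
CPM of 8 genes in the siNC and siPiezo1 libraries (bars, mean; lines, SD; symbols, replicates, n = 3 per group). Piezo1 and Ccnd1 are lower in all siPiezo1 libraries and highest in siNC 2, 1600014C10Rik is the gene past the threshold, and S100a9 is at 1044 CPM in siNC 2 alone.

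Of the 38 gene lists, 4 passed camera with the preset correlation. Of the genes of alternative macrophage activation, 15 of 16 tested members had a log2 fold change below 0, with a median of -0.45 (camera adjusted p = 2.25e-05). The call was lost with an estimated correlation (adjusted p = 0.246) and with fry (adjusted p = 0.105), and without siNC 2 the median was -0.23, with 13 of 16 members below 0. The estimated correlation of this list was -0.01, below the preset 0.01, so a higher correlation between its genes did not cause the loss. Mrc1, the mannose receptor CD206, stood at 199, 198 and 196 CPM in siNC and at 61.4, 99.4 and 60.3 CPM in siPiezo1, a log2 fold change of -1.42 ± 0.20 (SE). Il4ra, the interleukin-4 receptor chain, had -0.30 ± 0.10, Stab1 had -0.40 ± 0.18 and Ccl22, under 4 CPM throughout, had -2.42 ± 0.82 (SE). Ccl22 had -0.99 ± 0.71 without siNC 2, and there Stab1 had -0.58 ± 0.09 and passed the threshold (SE, adjusted p = 0.0290 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Genes of cholesterol synthesis and uptake had log2 fold changes below 0 in 23 of 23 tested members, with a median of -0.34 (camera adjusted p = 3.73e-14). This call was also lost with an estimated correlation (adjusted p = 0.579) and with fry (adjusted p = 0.296). Fdps, which makes the farnesyl diphosphate used for sterols, stood at 61.7, 48.3 and 67.0 CPM in siNC and at 40.6, 40.0 and 40.2 CPM in siPiezo1. The log2 fold changes were -0.69 ± 0.15 for Hsd17b7, -0.55 ± 0.13 for Fdps and -0.57 ± 0.16 for Sqle (SE). No single member of either list passed the threshold over all genes. Adjusted over the list alone, 1 member of the activation list (Mrc1) and 3 of the cholesterol list (Hsd17b7 and Fdps among them) were lower.

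The other lists past the camera threshold were glycolysis and hypoxia response, with 22 of 27 members above 0 and a median of 0.16 (camera adjusted p = 0.00534), and the neutrophil markers, with 14 of 16 members below 0 and a median of -1.38 (camera adjusted p = 0.000357). Both calls were lost with an estimated correlation (adjusted p = 0.833 for each) and with fry (adjusted p = 0.887 and 0.835). In the first, Pdk1 had a log2 fold change of 0.45 ± 0.14, Aldoa 0.21 ± 0.09, Pfkp 0.27 ± 0.14 and Gapdh 0.37 ± 0.17 (SE), the last with counts shared among 43 near-identical copies. In the second, Cebpe, S100a9, Elane and Ltf were highest in siNC 2, which for Elane held 46.2 CPM against at most 3.56 in any other library. Without siNC 2 the neutrophil median was 0.01 and the camera adjusted p was 0.973. The glycolysis call was lost without siNC 1 (median -0.002, camera adjusted p = 0.413), siNC 3 (0.04, 0.172) or siPiezo1 3 (0.10, 0.120). No member of either list passed the gene threshold, over all genes or adjusted over the list alone. Camera with an estimated correlation and fry called 0 of the 38 lists. Only camera with the preset correlation was checked on a simulated shift of a list. The losses with the other tests therefore do not show that a list is unchanged.

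The lists closest to the study's question did not pass camera with all 6 libraries. Of 17 G1 cyclin and CDK genes, 0 passed over all genes in edgeR's quasi-likelihood test, and adjusted over the list alone 1 was lower, Ccnd1. DESeq2 with all 6 libraries called Ccnd1 over all genes (adjusted p = 0.00269, Benjamini-Hochberg). The median log2 fold change of the G1 list was -0.03 (camera adjusted p = 0.535). The mitosis list (37 genes, median 0.09, camera adjusted p = 0.136), the DNA replication list (34 genes, -0.08, 0.932), the CDK inhibitors (7 genes, 0.20, 0.310) and the PI3K-AKT pathway (35 genes, -0.02, 0.842) had no member past the threshold, over all genes or adjusted over the list alone. Members with the smallest p were Bub1b and Foxm1 in the first, with log2 fold changes of 0.29 ± 0.24 and -0.61 ± 0.40 (SE), and Gins3 and Rfc3 in the second, with 0.38 ± 0.29 and 0.18 ± 0.14 (SE). Bub1b and Gins3 had 0.59 ± 0.14 and 0.73 ± 0.20 (SE) without siNC 2, not past the threshold. The mitosis list stood higher in siNC 2 than in siNC 1 and 3, by a median of 1.09 on the log2 scale, and the replication list by 1.01. Without siNC 2 camera called mitosis (median 0.59, camera adjusted p = 5.38e-19), replication (0.38, 3.19e-10) and the G1 genes (0.18, 0.0358), each higher in siPiezo1, and without siPiezo1 1 it called mitosis (0.24, camera adjusted p = 0.000455; with an estimated correlation and all 6 libraries, adjusted p = 0.948). With an estimated correlation none of the calls without siNC 2 held (adjusted p = 0.420, 0.420 and 0.474 with an estimated correlation). Without siNC 2, 13 of the 17 G1 genes were above 0. Over all genes 1 of them was then higher and 1, Ccnd1, lower in edgeR's quasi-likelihood test. Adjusted over the list alone, 5 were higher and 1 lower.

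Median log2 fold changes of the lists of mechanical sensing were 0.24 for YAP and TAZ targets, -0.03 for mechanosensitive channels, -0.03 for calcium and calcineurin signalling, 0.02 for cytoskeleton and integrin adhesion, -0.21 for immediate early genes and -0.18 for Wnt and beta-catenin. Fos, an immediate early gene, stood at 64.0, 57.4 and 60.9 CPM in siNC and at 40.2, 43.4 and 40.0 CPM in siPiezo1 (log2 fold change -0.56 ± 0.09, SE), and was the member lower adjusted over the list alone, there and in the osteoclast list. Piezo1 was the only such member among the channels. The immediate early median turned to 0.09 without siNC 2, and camera called the list lower without siNC 1 (camera adjusted p = 0.000686), siNC 3 (0.00541) or siPiezo1 1 (0.0222). With all 6 libraries its adjusted p was 0.833 with an estimated correlation and 0.887 with fry. Fos passed the threshold without siNC 2 (adjusted p = 0.0164 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The Wnt list was called lower without siNC 2 (camera adjusted p = 0.0233, and adjusted p = 0.420 with an estimated correlation).

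In the macrophage lists the medians were 0.02 for identity, -0.84 for inflammatory cytokines and M1 markers, 0.09 for interferon-stimulated genes, 0.19 for MHC class II presentation, -0.15 for osteoclast differentiation, 0.06 for lysosome and -0.22 for extracellular matrix and proteases. Several of these directions rest on siNC 2, in which the inflammatory list stood a median of 1.82 on the log2 scale above siNC 1 and 3. Without it the median was 0.21 for the inflammatory list (camera adjusted p = 3.22e-05), 0.30 for extracellular matrix (0.0168), -0.13 for interferon-stimulated genes (0.00187) and -0.09 for identity (0.00122), each on the other side of 0. For identity the camera direction was lower with all 6 libraries too, where the mean was -0.06. These calls were lost with an estimated correlation (adjusted p = 0.420, 0.420, 0.530 and 0.420). Camera called the opposite directions when other libraries were left out: the inflammatory list lower without siNC 1 (camera adjusted p = 3.19e-05), siNC 3 (0.000749) or siPiezo1 3 (0.0452), extracellular matrix lower without siNC 1 (0.0118) or siNC 3 (0.00518), and interferon-stimulated genes higher without siNC 1 (0.000542) or siNC 3 (0.000755). MHC class II presentation was called higher without siNC 1 (camera adjusted p = 0.0326) or siNC 3 (0.0415), and without siNC 2 its median was 0.10 (0.396). With an estimated correlation and all 6 libraries the adjusted p was 0.833 for the inflammatory list, 0.833 for extracellular matrix, 0.946 for interferon-stimulated genes and 0.579 for MHC class II.

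Metabolic and stress lists had medians of 0.02 for liver X receptor targets, 0.03 for oxidative phosphorylation, 0.01 for the cytosolic ribosome, -0.15 for the unfolded protein response, -0.02 for heat shock, 0.03 for p53 targets, 0.08 for NRF2 targets, -0.04 for apoptosis regulators, -0.03 for FOXO targets and -0.02 for the RNA interference machinery. Without siNC 2 the median was -0.10 for the ribosome (camera adjusted p = 0.0086, and adjusted p = 0.548 with an estimated correlation) and 0.10 for the unfolded protein response. Camera called the unfolded protein response lower without siNC 1 (camera adjusted p = 0.00124) or siNC 3 (0.00518), the ribosome higher without siNC 3 (0.0415) and NRF2 targets higher without siPiezo1 2 (0.00676). With an estimated correlation and all 6 libraries their adjusted p was 0.946, 0.977 and 0.833. Abcg1, a cholesterol exporter among the liver X receptor targets, stood at 83.4, 64.0 and 78.2 CPM in siNC and at 127, 112 and 122 CPM in siPiezo1 (0.68 ± 0.12, SE), and was higher adjusted over the list alone. Without siNC 2 Abcg1 passed over all genes (adjusted p = 0.0153 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Other-cell markers had medians of 0.20 for fibroblasts, -0.58 for lymphocytes, 0.11 for dendritic cells, -0.69 for mast cells, basophils and eosinophils, -0.69 for erythroid cells and megakaryocytes, and 0.08 for endothelial and epithelial cells, where Kdr was higher adjusted over the list alone (4.25, 4.67 and 5.67 CPM in siNC, 9.82, 8.05 and 7.34 in siPiezo1). Without siNC 2 the median was 0.60 for fibroblasts, with 10 of 10 members above 0 (camera adjusted p = 0.0151, and adjusted p = 0.420 with an estimated correlation), 0.35 for mast cells, basophils and eosinophils and 0.34 for erythroid cells and megakaryocytes. With all 6 libraries the median, the mean and the camera direction differed in sign for the lists of DNA replication, FOXO targets, cytoskeleton, macrophage identity, heat shock, fibroblasts, dendritic cells, and endothelial and epithelial cells. None of the lists of mechanical sensing, macrophage states, metabolism, stress or other cells given in these medians passed camera with all 6 libraries, and no member passed over all genes there.

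The description without siNC 2 was added after the data were seen, although leaving out each library was planned before. Without siNC 2, 178 genes passed the threshold of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 106 higher and 72 lower in siPiezo1. The largest falls by the naming rule were those of Pcdhgb7, Mamdc2 and Adra1a. Their log2 fold changes were -2.64 ± 0.23, -2.24 ± 0.26 and -1.59 ± 0.23 (SE). The counts of Pcdhgb7 are uncertain: Pcdhgc3 (33.4 CPM on library totals, against 3.52) covers 45.0% of its exon bases on the same strand. Apoe fell by 1.49 ± 0.06 (SE) on the log2 scale and Pltp, a phospholipid transfer protein, by 1.51 ± 0.09. Cacna1a and B3galnt1 had -1.28 ± 0.18 and -1.22 ± 0.18 (SE). Lpl, lipoprotein lipase, taken as a list member, fell by 0.99 ± 0.06. Aak1, Zfp451, Ap5b1, Clmp and Slpi rose, by 2.01 ± 0.14, 1.07 ± 0.10, 1.27 ± 0.13, 1.21 ± 0.17 and 1.05 ± 0.12 (SE), and Ednrb, Gatm and Pde2a fell by 1.15 ± 0.14, 1.03 ± 0.17 and 1.02 ± 0.17. The counts of Pltp and Pde2a are uncertain: Ctsa (844 CPM on library totals, against 115 for Pltp) covers 19.3% of the exon bases of Pltp on the opposite strand, and Gm45837 (23.3 against 18.1 for Pde2a) covers 64.3% of those of Pde2a on the same strand. Of the 178 genes, the library left out lay on the side of the other siNC libraries for 61, within the siPiezo1 range for 18 and beyond the siPiezo1 libraries for 99. It lay beyond them for Mamdc2, Adra1a, Apoe, Pltp, Cacna1a, B3galnt1, Lpl, Aak1, Egln3, Ap5b1, Cxcl3 and Slpi, and within their range for Clmp. The library left out lay on the siNC side for Pcdhgb7, Gbp10, H2-M2, Wnt6, Zfp451, Ednrb, Gatm and Pde2a. DESeq2 with 6 libraries called 37 of the 178. In simulated data of this size 13.5% of calls were false. That share holds for a set number of changed genes and counts only calls on genes simulated as unchanged. It does not cover genes that differ between these libraries for a reason other than the knockdown. The share of the 178 genes that does not come from the knockdown was therefore not estimated.

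Among the lists without siNC 2, cholesterol genes stayed lower in 23 of 23 members, with a median of -0.49, and 6 fell over all genes (18 adjusted over the list alone), among them Hmgcs1, Sqle and Fdps. Hmgcs1 fell by 0.97 ± 0.09 (SE) and Sqle by 0.72 ± 0.09. In siNC 2 itself the list stood a median of -0.39 from siNC 1 and 3. Glycolysis and hypoxia genes were above 0 in 27 of 27 members, with a median of 0.35, and 6 rose (18 adjusted over the list alone), among them Egln3, Ero1l, Ldha and Pdk1. This list also stood higher in siNC 2 than in siNC 1 and 3, by a median of 0.53, and Egln3 was at 44.0 CPM in siNC 2 against 16.4 to 26.5 in siPiezo1. Of the macrophage identity genes 6 fell, among them Apoe, Lpl, Fcgr1, Adgre1 and Fcgr3, and Cd33 rose. The mitosis and replication medians were 0.59 and 0.38, with 0 members past the threshold over all genes and 22 and 7 higher adjusted over the list alone. Camera called 13 lists without siNC 2, and 0 with an estimated correlation. With an estimated correlation the camera adjusted p was 0.420 for cholesterol, glycolysis, mitosis and replication, a tie made by the adjustment. Their unadjusted p in the same camera test was 0.0241, 0.0850, 0.151 and 0.188. Fry called 5 lists: cholesterol (fry adjusted p = 0.0426), macrophage identity (0.0122), Wnt and beta-catenin (0.0122), liver X receptor targets (0.0367) and mechanosensitive channels (0.0426). The channel list holds the silenced gene Piezo1, its only member past the threshold, and had 6 members above and 8 below 0. The liver X receptor list had 6 above and 6 below, so neither shows a shared direction. Macrophage identity was also mixed, with 13 above and 17 below, and Wnt and beta-catenin had 3 above and 13 below. Fry did not call glycolysis (adjusted p = 0.0857), mitosis (0.185) or replication (0.185).

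**Figure D3:**
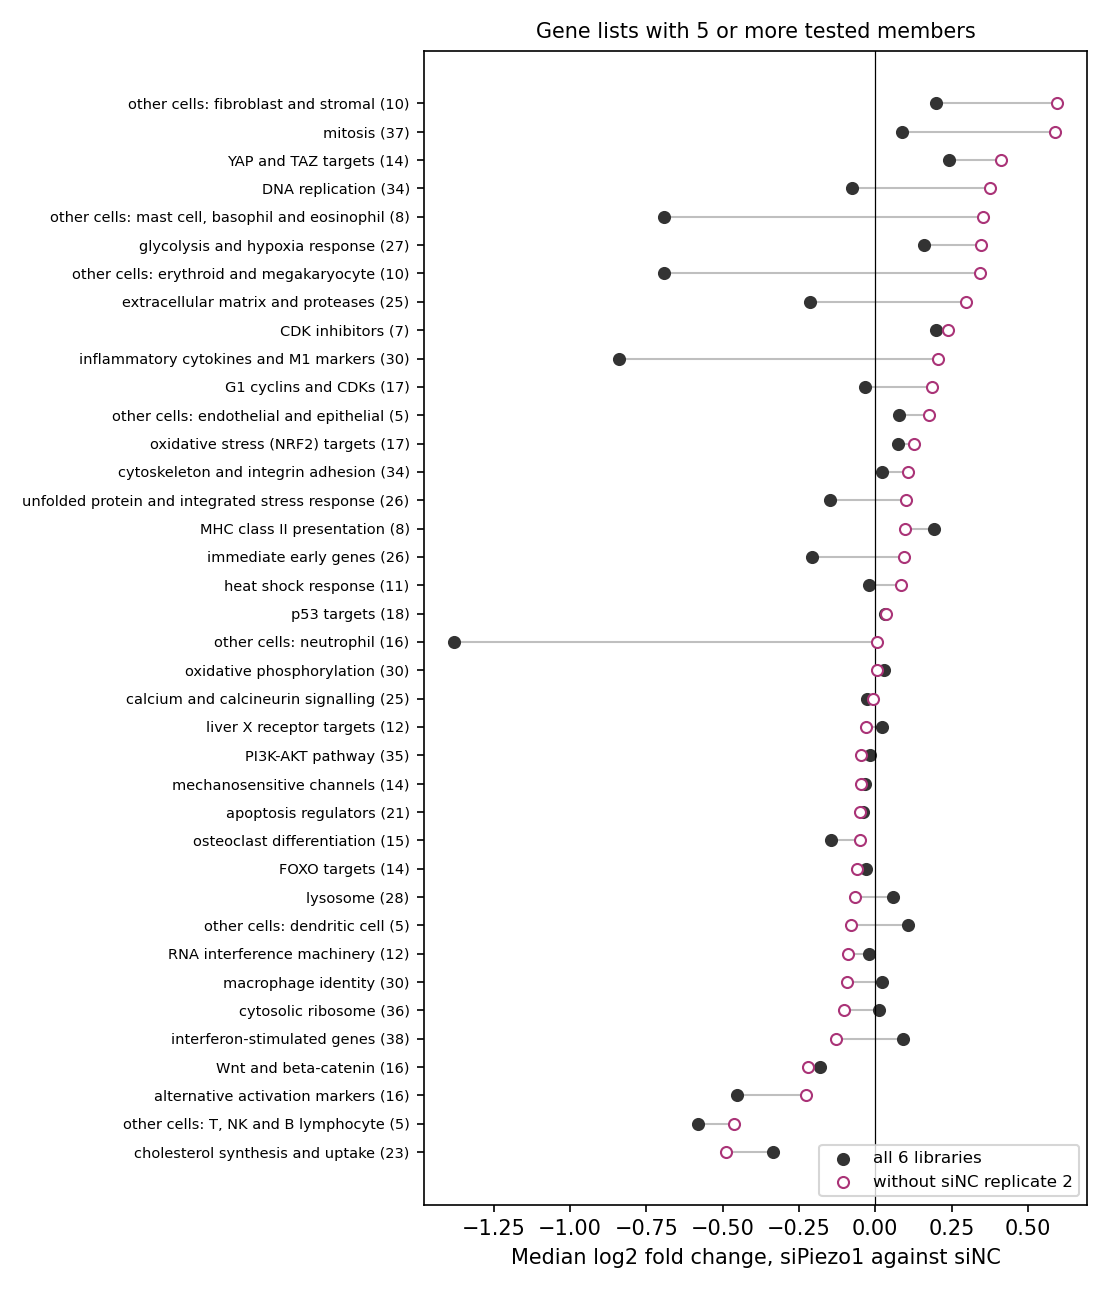
Median log2 fold change, siPiezo1 against siNC, of the 38 lists (tested members in brackets) with all 6 libraries (filled) and without siNC replicate 2 (open). Cholesterol genes are below 0 in both, at -0.34 and -0.49, and neutrophil markers move from -1.38 to 0.01.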

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

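Library weights, counts divided by 4 and the naming of genes without siNC 2 were chosen only after the data were seen. The cause of a change below was not tested unless stated.

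With edgeR's quasi-likelihood test 0 genes were higher and 1 lower in siPiezo1. Genes lower were 0 with library totals only, 0 with an adjusted p under 0.01 and 0 against a fold of 1.2. DESeq2 called 46 higher and 42 lower, and limma-voom with library weights 1 higher and 3 lower; siNC 2 had a weight of 0.200 there, against 1.26 to 1.52. Leaving out 1 library gave 0 (without siNC 1) to 106 genes higher and 0 to 72 lower, the highest without siNC 2. The Piezo1 log2 fold change was below 0 in all alternatives run; it passed with DESeq2 (-0.98), and leaving out 1 library gave -1.09 (without siNC 1) to -0.73 (without siNC 2, the one that passed).

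With the replicate number as a block, 0 genes were lower and 0 higher (499 at an unadjusted p under 0.05), and camera called 4 lists. Deviations of libraries with the same number correlated at 0.030, -0.062 and -0.086 across genes, and those with different numbers at -0.073 to 0.123. No pairing by number was therefore detected. A shared animal, culture or day is not excluded, since the labels name none and the siNC deviations include the library that stood apart.

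Of the gene lists, 4 passed camera, 0 with an estimated correlation and 0 with fry; leaving out 1 library gave 4 (without siPiezo1 3) to 13 (without siNC 2). Leaving out siNC 2 turned the direction of the camera test, with a call, for 5 lists, and the neutrophil markers lost their call with no direction left. The medians there, with the lowest and highest over the libraries left out, were 0.18 for G1 cyclins and CDKs (-0.14 to 0.18), -0.13 for interferon-stimulated genes (to 0.21), 0.21 for inflammatory cytokines (from -1.11), -0.10 for the cytosolic ribosome (to 0.10), 0.30 for extracellular matrix (from -0.39) and 0.006 for neutrophil markers (from -1.78). Values changed sign with no call on either side for 14 of 1381 gene values and 34 of 418 list values. The median log2 fold change of all genes was -0.011, -0.014 and -0.021 with TMM, DESeq2's size factors and library totals.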

Other observations

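All tests here except that of siRNA seed matches were chosen only after the result was seen.

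The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1 gene, the highest other 3, and 5 of the 10 splits gave as many as the real one. Without siNC 2 the 5 libraries also make 10 splits, again too few. The real split gave 178 genes, the highest other 8, and 1 of the 10 splits, the real one, gave as many.

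Why siNC 2 stands apart was set against 4 technical explanations. Its total count ranks 5 of 6 from the lowest, within the range of the others, which argues against depth. Its Piezo1 CPM is 2.52 times that of the highest siPiezo1 library, which argues against a siPiezo1 library under a siNC label. Macrophage identity genes moved by a median of -0.41 (90% bootstrap bounds -0.54 to -0.19, n = 30 genes). That is short of the -1 that dilution alone would need for the genes more than 2-fold below all other libraries. A smaller dilution by other cells, beside another cause, stays open. Neutrophil genes stood a median of 2.53 higher (bounds 1.61 to 2.83), with 14 of 16 above 0, but this rise is the pattern itself and does not separate RNA of neutrophil-lineage cells from induction in the macrophages. S100a9 stood at 1044 CPM, while Csf3r stood at 58.7 CPM against 121 and 132 in siNC 1 and 3, and both explanations stay open, as no biological explanation was tested.

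The differences of the siPiezo1 libraries and of siNC 2 from siNC 1 and 3 were shared in part. With separate controls the log2 differences correlated at 0.353 and 0.356 across 10054 genes, which are not independent replicates. For single siPiezo1 libraries the lowest correlation was 0.198, so many genes did not follow the shared direction. Simulated unchanged groups gave 0.006, but their noise was independent between libraries, with siNC 2 no noisier than the others. A value near 0 was therefore fixed in advance there. With the mean of siNC 1 and 3 as the control of both, r was 0.551 (covariance 0.122), against 0.440 (0.0348) in the simulation. This is consistent with a shared state of the cultures beside the knockdown, and the same picture would arise if siNC 1 and 3 were the libraries apart. Part of the 178 differences found without siNC 2 may therefore not come from the knockdown, as for the 99 genes where siNC 2 lay beyond the siPiezo1 libraries.

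Off-target silencing by the siRNA could lower genes whose 3' UTRs hold its seed match. The siRNA sequence was not used here, so 5067 stretches of 7 bases from the Piezo1 mRNA were searched in the 3' UTRs of 9577 genes. The most extreme stretch gave a permutation p of 0.323 over 1000 shuffles with 6 libraries and 0.649 without siNC 2. The most negative mean shifts were -0.08 and -0.06 on the log2 scale, below the -0.05 set in advance for excluding such an effect, so the test leaves it open.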
